A study of Mus musculus with 18 samples.

How the data were processed

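Gene expression was measured by RNA sequencing in 18 libraries of bone marrow-derived macrophages, 9 wild-type and 9 RelA-TA-KI, covering unstimulated cells and 0.5, 1, 3 and 8 h of LPS or TNF. Per the labels' protocols, libraries were made from poly(A) RNA with the KAPA Stranded mRNA-Seq kit and read as single ends of 50 bases. The authors deposited a table of raw gene counts that are not normalized, 1 column per library, with mm10 coordinates. Per the submitters' processing notes, reads were trimmed with cutadapt 1.12, aligned with STAR and counted with featureCounts 1.5.0. The strand setting and the annotation release are not given in the sources used here, so counts of overlapping or antisense genes are less certain than others. The values were checked to be whole numbers. The table had 45706 genes, of which 24529 were at 0 in every library, and 563 identifiers had no symbol.

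Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, leaving 11308. With 1 library per genotype and condition, condition entered as a block and the residual came from how the genotype pairs differed (8 residual degrees of freedom for the average genotype effect and the responses, 6 for effects by stimulus or by phase). The common biological coefficient of variation was 0.111. Comparisons were the genotype effect (knock-in minus wild-type) over the 9 conditions, over the 4 LPS times and over the 4 TNF times, and the differences of this effect between LPS and TNF, between stimulated and unstimulated cells, and between late (3 and 8 h) and early (0.5 and 1 h) times. The response to each stimulus was tested with both genotypes together by an F test over the 4 times, and LPS was compared with TNF at matched times. Direction in a response is that at the time with the largest absolute change. CPM (counts per unit of library size, scaled as in edgeR) used TMM-scaled totals, and log2 CPM a prior count of 0.5.

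In total 20 gene lists were written from textbook knowledge: NF-kB feedback and family genes, inflammatory cytokines, chemokines, interferon-stimulated genes, immediate early genes, survival and adhesion targets, late LPS effector genes, antigen presentation, TLR4 and TNF receptor signalling, macrophage identity, proliferation, cholesterol synthesis, glycolysis, extracellular matrix and stromal cells, and markers of neutrophils, dendritic cells, lymphocytes, mast cells, erythroid cells and sex. Hdc is in 2 of them. Lists with enough genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over the lists of a comparison. For responses camera used the mean of the 4 times. In single pairs of libraries a list's median ratio is given without a test. Its place among 10000 random lists matched on mean expression was computed and is not used, since it leaves out the correlation between genes and the spread between libraries. Induced genes passed the F test with a log2 fold change of 1 or more at any time.

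Named genes passed the threshold, had a mean log2 CPM of 1 or more and the same sign in all but at most 1 pair, leaving out numbered gene models and pseudogenes. For late against early effects each pair was a difference of genotype ratios, 3 h minus 0.5 h or 8 h minus 1 h of a stimulus. Of these the 12 with the largest change in each direction are given (8 for LPS against TNF and for differences of effects), with up to 3 members per list, or the most expressed member where none passed. A few genes that this rule selects are not reported here, and they remain in the counts and list tests. Ratios against groups at 0 counts use a floor of 3 counts over the group, and groups with 1 to 3 counts have 95% counting intervals.

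Alternatives were DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 9 libraries, DESeq2 1.42.0, limma-voom, leaving out each condition with both its libraries, and a log2 fold change of 2 for induced genes. The comparisons, lists, naming rule and these alternatives were fixed before the data were examined. Scaling by library totals was added after the data were seen. On simulated data, with 67, 67 and 66 genes changed by 0.5, 1 and 2 on the log2 scale, the average genotype effect recovered 73.1%, 86.6% and 100.0% of them, and the difference between late and early effects 16.4%, 64.2% and 86.4%. False calls made up 5.98% of the simulated calls for the average genotype effect and 5.13% for late against early effects. For the genotype effect they made up 7.93% after LPS, 7.55% after TNF and 4.69% for its difference between LPS and TNF. They were 10.9% for the LPS response, 7.64% for the TNF response and 6.21% for LPS against TNF. All of these but the 4.69% exceeded the adjustment threshold, so lists of calls may hold more false calls than it implies. Figures were drawn with matplotlib 3.10.9.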

Results

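Poly(A) RNA was sequenced from mouse bone marrow-derived macrophages, cells grown from C57BL/6 bone marrow in medium containing 30% L929-cell conditioned medium. Wild-type cells were compared with cells named RelA-TA-KI, a knock-in of Rela, the gene of the NF-kB subunit RelA. The series title concerns how RelA activates its target genes in the inflammatory response. Cells were left unstimulated or received lipopolysaccharide (LPS, 100 ng/ml), which acts through TLR4, or the cytokine TNF (10 ng/ml), and were collected 0.5, 1, 3 and 8 h later. This gave 9 conditions with 1 library per genotype and 18 libraries. No condition had a replicate, so tests took their spread from how the matched pairs of genotypes differed across conditions. No separate animals or cultures were named, so a p-value measured consistency over these libraries and not between mice, and genotype could not be separated from culture. Totals ranged from 4663650 to 6721917 counts per library, with means of 5608518 in wild-type and 5187884 in knock-in libraries. The 10 most abundant genes held 11.3% to 14.2% of the counts, and 13774 to 15261 genes were detected per library. Fewer genes were detected in the knock-in library in 9 of 9 pairs (14319 against 15261 before stimulation), including 8 h of LPS, where its total was the higher one (13774 against 13941 genes). The knock-in library at 3 h of TNF stood apart, with the lowest total (4663650 counts), the highest share of a single gene (Gm42418, 3.36%) and the lowest mitochondrial share (0.404%). In a multidimensional scaling plot the leading axis, with 63.9% of the variance, ran from unstimulated cells to 8 h of LPS. The next axis, with 8.58%, placed the knock-in library above its wild-type partner in each of the 9 conditions. Of 45706 genes in the table, 11308 were tested. Log2 fold changes are given with a standard error unless stated otherwise. It was worked back from the test, as the absolute change over the square root of the F statistic. It is therefore approximate, above all for large changes from few counts.

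Rela (ENSMUSG00000024927.7, chromosome 19, 5637483 to 5648130, mm10) was transcribed in every library. Unstimulated cells held 62.5 CPM in wild-type and 67.4 CPM in knock-in cells. After LPS, wild-type values at 0.5, 1, 3 and 8 h were 79.4, 128, 283 and 166 CPM, and knock-in values were 82.4, 105, 181 and 144 CPM. After TNF, wild-type values at the same times were 77.3, 109.7, 138 and 119 CPM, and knock-in values were 69.99, 92.9, 121 and 104 CPM. These rest on 376 to 1327 reads per library. Rela was lower in the knock-in by a small margin over the 9 pairs (log2 fold change -0.20 ± 0.06, adjusted p = 0.049). A knock-in that keeps the transcript is not visible in gene counts, so these values do not check the genotype labels.

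LPS changed most of the transcriptome within 8 h in both genotypes together. Inflammatory mediators and interferon-inducible genes were among those that rose, each in both genotypes: Ccl5, a T-cell attracting chemokine, rose by 12.32 ± 0.82 on the log2 scale at 8 h, the inducible nitric oxide synthase Nos2 by 12.69 ± 1.26, the co-stimulatory receptor Cd40 by 11.34 ± 1.40, and the chemokine Cxcl10 by 11.39 ± 1.20 at 3 h (2 libraries per condition). Several were at 0 counts before stimulation, and their folds are lower bounds set against 3 counts over the group. Cxcl9 rose at least 1177-fold, the cytokine Il6 at least 668-fold, Tgtp1 at least 414-fold, Pou3f1 at least 343-fold, Ifi214 at least 260-fold and Mir155hg, a microRNA host transcript, at least 222-fold. With 1 count before stimulation, Ifi208 stood 6998-fold higher (95% counting interval 1255 to 276500) and Ccl8 3597-fold higher (645 to 142160). Several genes went to 0 counts at 8 h, among them the RNA-modifying Rpusd2 (at least 16.1-fold lower), the DNA helicase Recql4 (15.7-fold), Tarbp1 (14.7-fold) and Sbk1 (11.2-fold). The same held for Sapcd2 (10.9-fold), Dhrs13 (10.1-fold), Dchs1 (7.59-fold), Etfbkmt (7.28-fold) and the clock factor Npas2 (6.17-fold). The clock repressor Nr1d1 and the Polycomb gene Cbx8 were at 0 counts at 3 h, at least 13.05-fold and 11.5-fold lower. Coro2b was at least 12.3-fold lower at 8 h, and its largest change was an increase of 0.73 when the 8 h pair was left out. These intervals and floors cover counting error only.

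Known target groups of TLR4 signalling rose nearly without exception after LPS. All 14 tested NF-kB feedback and family genes, 16 inflammatory cytokines, 15 chemokines, 30 interferon-stimulated genes, 18 survival and adhesion genes and 16 antigen presentation genes passed the test upward at the time of their largest change, and the counts adjusted over the list alone were the same. Among them were Nfkbiz (7.86 ± 0.70 at 1 h) and Tnip3 (8.62 ± 0.78) of the feedback list, the antiviral genes Ifit1 (9.91 ± 0.41 at 3 h, adjusted p = 9.5e-10) and Mx1 (10.20 ± 0.48), and Traf1 (9.68 ± 0.92). Immediate early genes, which respond without new protein synthesis, rose at 21 of 22 members, led at 0.5 h by Egr1 (6.24 ± 0.44), Fosb (5.66 ± 0.44) and Dusp1 (5.58 ± 0.56). Late LPS effector genes rose at 21 of 22 members, Acod1, the enzyme making itaconate, by 10.64 ± 0.87. Il12b, a subunit of IL-12 and IL-23, stood 1183-fold above 3 counts (404 to 5742), Csf3 rose at least 71.6-fold and Bcl2a1a at least 114.5-fold. Proliferation genes fell at 18 of 20 members (18, with 1 up, adjusted over the list alone), including Rrm2 (-4.39 ± 0.21), Cdc20 (-4.19 ± 0.25) and Ccna2 (-3.99 ± 0.11). The myeloid factor Cebpa fell (-4.74 ± 0.22) while the Fc receptor Fcgr1 rose by 5.11 ± 0.21, in a macrophage identity list with 10 members up and 5 down. Cholesterol synthesis genes fell at 12 and rose at 2 of 16, with Stard4 at -2.89 ± 0.11. Pfkfb3, a regulator of glycolysis, rose by 3.41 ± 0.15. Hk2 changed by 1.57 ± 0.22 at 3 h, and its largest change was -1.59 with library totals and -0.69 without the 3 h pair. Glycolysis had 5 members up and 2 down (4 and 1 adjusted over the list alone). TLR4 and TNF receptor signalling had 12 up and 3 down, Myd88 by 3.27 ± 0.17 and the co-receptor Cd14 by 2.60 ± 0.22 at 1 h.

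The F test over the 4 LPS times called 8159 genes, 4047 up and 4112 down at the time of their largest change. Camera on the mean of the 4 times called the NF-kB feedback genes up (median log2 fold change 2.46, adjusted p = 3.2e-09), with cytokines (median 4.41), chemokines (4.44) and interferon-stimulated genes (3.41, adjusted p = 2.6e-42). Proliferation was called down (-0.88, adjusted p = 7.3e-13). All list calls held with an estimated correlation, except survival and adhesion genes (adjusted p = 7.3e-10, and adjusted p = 0.0508 with an estimated correlation). Macrophage identity (adjusted p = 0.429), cholesterol synthesis (0.0509) and glycolysis (0.208) were not called. Of other cell types' markers, neutrophil genes had 5 up and 1 down of 11, Hdc of the mast cell list rose by 8.33 ± 0.31, and the dendritic cell list had only the migration receptor Ccr7 up (4.57 ± 0.52). Of 7 matrix genes Dcn rose (2.58 ± 0.74, 0 adjusted over the list alone), lymphocyte markers split 1 up and 1 down, and Xist did not pass (0.30, adjusted p = 0.081). Scaling decided the balance of calls: with library totals in place of TMM factors the split was 1973 up and 7853 down, 20.1% up against 49.6%, because a shift of -0.95 in the median of all genes separates the scalings. With library totals TLR4 and TNF receptor signalling turned to 7 up and 10 down, macrophage identity to 5 and 8, and glycolysis to 3 and 13. Matrix genes then had 0 up and 1 down, lymphocyte markers 0 up and 2 down, and Xist fell (-1.14).

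**Figure D1:**
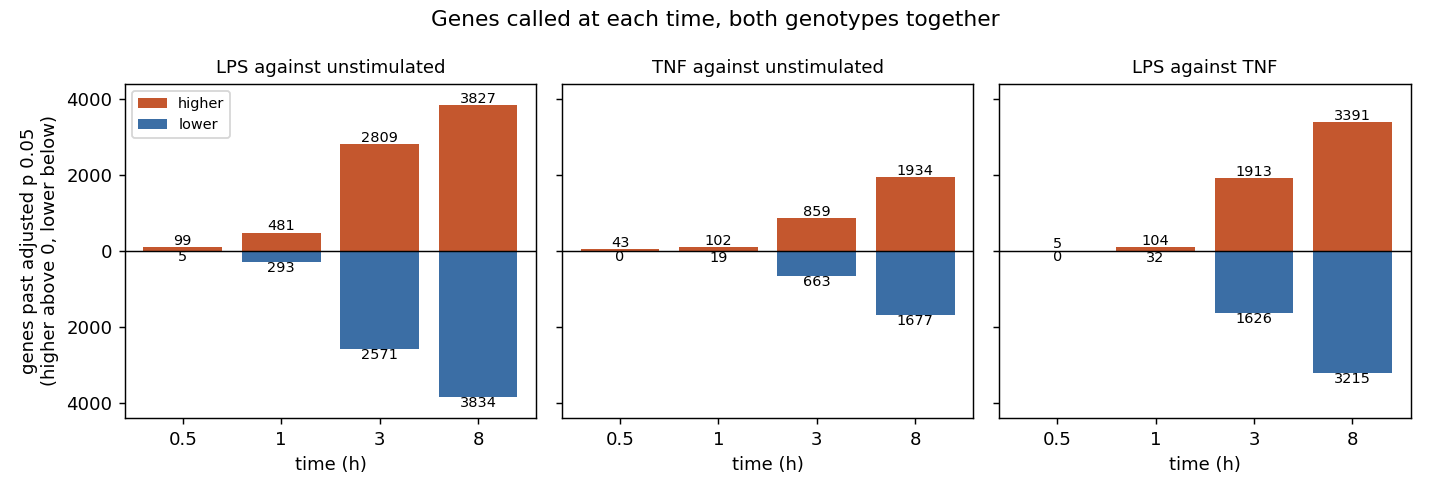
Number of genes past an adjusted p of 0.05 at each time (h, evenly spaced) for LPS against unstimulated, TNF against unstimulated and LPS against TNF, with both genotypes together under TMM scaling. Bars above 0 count genes that were higher and bars below 0 genes that were lower; LPS calls grow from 104 at 0.5 h to 7661 at 8 h and TNF calls from 43 to 3611.

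TNF induced an overlapping set of mediators to a smaller extent. Acod1 rose by 8.16 ± 0.81 at 8 h, Gbp5, an interferon-inducible GTPase, by 7.51 ± 1.26, Cd40 by 7.38 ± 1.43 and the antiviral gene Ifit2 by 7.18 ± 0.48 (adjusted p = 4.3e-07). Each was higher in both genotypes. Ifi206 rose by 7.09 ± 0.47. H2-M2 stood 391-fold above 3 counts (133 to 1899), Ifi208 444-fold above 1 count (79.2 to 17606), and the neutrophil chemokine Cxcl1 207-fold above 1 count at 0.5 h (36.7 to 8212). Cxcl9 was at least 25.8-fold higher, Pou3f1 at least 24.9-fold, Rasgrp1 at least 21.04-fold and Bcl2a1a at least 14.6-fold. The laminin gene Lama3 fell (-4.63 ± 0.33), as did the BMP target Id1 (-3.55 ± 0.39), the ERK phosphatase Dusp6 (-3.38 ± 0.54 at 3 h) and the flagellin receptor Tlr5 (-3.37 ± 0.63). Rgs7bp (-3.29 ± 0.33), Klhl23 (-3.27 ± 0.53) and Rnf150 (-2.85 ± 0.12) also fell. Also lower by counts were Coro2b (20.2-fold at 3 counts, 6.66 to 100.0), Slco2b1 (13.6-fold at 2 counts, 3.49 to 117) and Rtn4rl1 (11.3-fold at 2 counts, 2.85 to 97.3). Flt4 and Lad1 stood on 7 and 4 reads before stimulation, at least 1.89-fold lower at 3 h and at least 1.19-fold lower at 1 h. Their direction depended on the fit, with a largest change for Flt4 of 2.33 without the 3 h pair, and for Lad1 of 3.43 with DESeq2, 3.19 with limma-voom and 3.44 without the 1 h pair.

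Interferon-stimulated genes rose at 30 of 30 members after TNF, Ifit1 by 6.93 ± 0.37. Chemokines rose at 13 of 15, antigen presentation genes at 14 of 16 (16 adjusted over the list alone), survival and adhesion genes at 14 of 18 (15), late LPS effector genes at 13 of 22 (14), NF-kB feedback genes at 9 of 14 (11) and cytokines at 7 of 16 (9). Examples were Il1b (5.93 ± 0.64 at 0.5 h), Nfkbiz (4.35 ± 0.65 at 0.5 h), Tnf (3.70 ± 0.74 at 3 h), Traf1 (6.36 ± 0.96) and Saa3 (6.46 ± 0.47). Immediate early genes rose at 20 and fell at 1 of 22, with Egr1 at 5.07 ± 0.42 and Fosb at 4.97 ± 0.46 at 0.5 h. Egr1 was lower by its largest change of -1.76 when the 0.5 h pair was left out, and Tap1 (3.08 ± 0.24) and Fcgr1 (2.03 ± 0.19) gave -0.20 and -0.84 without the 8 h pair. Proliferation genes fell at 19 of 20 members (20 adjusted over the list alone), with Rrm2 at -2.20 ± 0.16 and Mcm2 at -1.88 ± 0.12. Cholesterol synthesis genes rose at 5 and fell at 1 of 16 (6 and 1 adjusted over the list alone), with Hmgcs1 at 0.63 and Fdft1 at 0.52, but stood at 1 up and 3 down with library totals. The F test called 3434 genes, 1893 up and 1541 down, and with library totals 1322 up and 2853 down (31.7% up against 55.1%, median shift -0.25). Without the 8 h pair it called 1100.

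By camera, interferon-stimulated genes (adjusted p = 2.8e-34), NF-kB feedback genes (8.1e-14), immediate early genes (1.7e-17), survival genes (4.1e-14), antigen presentation (2.0e-14), late effector genes (2.9e-11), cytokines (6.0e-06), chemokines (6.0e-07) and TLR4 and TNF receptor signalling (0.0218) were called up and proliferation down (2.5e-13), each also with an estimated correlation. The signalling list had 6 up and 0 down of 20 (4 and 2 with library totals). Not called were macrophage identity (5 up and 5 down, or 4 and 7 with library totals, adjusted p = 0.913), cholesterol synthesis (0.0509), glycolysis (4 up and 3 down, or 2 and 3 with library totals, 0.333) and matrix genes (0 up and 2 down, or 0 and 4 with library totals, 0.102), with Fn1 at -1.07 ± 0.24. Gapdh, called over the 4 times, stood at -1.16 ± 0.32 at 0.5 h and at 0.51 without that pair. Of other cell types' markers Mmp8 of the neutrophil list fell (-0.89 ± 0.13) and Cd209a of the dendritic cell list was at least 5.17-fold lower, while its member Zbtb46 rose by 1.80 ± 0.47 at 3 h (the list had 0 up and 1 down with library totals). Hdc, Il7r and Xist did not pass.

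Secreted mediators and interferon-stimulated genes were higher after LPS than after TNF when both were averaged over matched times. Ifnb1, the gene of interferon beta, was higher by 7.30 ± 1.21 (adjusted p = 0.00083, higher in 8 of 8 pairs), Il6 by 5.89 ± 0.66, Il12b by 4.83 ± 0.68, the vasoconstrictor gene Edn1 by 4.79 ± 0.74 (each in 7 of 8 pairs), Cxcl10 by 4.76 ± 0.45, Nfkbiz by 4.59 ± 0.29 and the anti-inflammatory cytokine Il10 by 4.29 ± 0.56. Ccl5 was 25.96-fold higher (adjusted p = 3.7e-05, 8 of 8 pairs). Csf3 stood 154-fold above 1 count after TNF (27.2 to 6142). All 30 interferon-stimulated genes were higher after LPS, including Oasl1 (4.19 ± 0.23), Ifit1 (3.58 ± 0.16) and Rsad2 (3.25 ± 0.16), as were 16 of 16 cytokines and 15 of 15 chemokines. So were 16 of 18 survival genes (10 with library totals), 11 of 14 NF-kB feedback genes with Tnfaip3 (2.29 ± 0.42), 15 of 22 late effector genes with Ptgs2 (3.96 ± 0.24), 14 of 22 immediate early genes with Zfp36 (2.55 ± 0.12) and 11 of 16 antigen presentation genes with Tap1 (1.44 ± 0.12) and Nlrc5. Lower after LPS were Dchs1 (-3.36 ± 0.49, 7 of 8 pairs), Sox7 (-2.45 ± 0.66, 7 of 8), Ccsap (-2.34 ± 0.18), Irf2bp2 (-2.13 ± 0.17), the p53 target Sesn1 (-2.06 ± 0.11), Cdca7 (-1.98 ± 0.17), Recql4 (-1.98 ± 0.39, 7 of 8) and Dhrs13 (-1.90 ± 0.44). Proliferation genes were lower at 16 and higher at 2 of 20, with Cdc20 at -1.17 ± 0.09, and cholesterol synthesis genes lower at 12 and higher at 1 of 16, with Mvd at -1.11 ± 0.18. At 0.5 h 5 genes separated the stimuli, all higher after LPS and chosen after their values were seen: Btg2 (1.10 ± 0.13), Atf3 (0.88 ± 0.13), Zfp36 (1.98 ± 0.23), Phlda1 (1.62 ± 0.18) and Ier3 (1.87 ± 0.18). No gene was called lower at that time by edgeR, with 274 genes in all under an unadjusted p of 0.05.

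The test called 5529 genes, 2681 higher and 2848 lower after LPS, and the count fell to 2489 without the LPS 8 h pair and 1932 without the TNF 8 h pair. With library totals 1172 were higher and 7057 lower (14.2% higher against 48.5%, median shift -0.31). Camera called interferon-stimulated genes (adjusted p = 1.9e-46), chemokines (2.5e-21), cytokines (1.6e-11), immediate early genes (1.5e-10) and late effector genes (3.4e-10) higher and proliferation lower (4.8e-07), each also with an estimated correlation. Calls for NF-kB feedback genes (adjusted p = 8.4e-06), survival genes (2.6e-06), antigen presentation (1.9e-07), TLR4 and TNF receptor signalling (0.0203) and cholesterol synthesis (6.4e-06) were lost, at adjusted p = 0.121, 0.128, 0.121, 0.0636 and 0.144 with an estimated correlation. TLR4 and TNF receptor signalling had 10 higher and 4 lower (7 and 9 with library totals), macrophage identity 9 and 2 (2 and 9), and glycolysis 4 and 2 (4 and 11). Counts adjusted over the list alone differed from these by at most 2 genes in a direction. Neutrophil markers were higher at 6 of 11 and matrix genes at 4 of 7, and with library totals at 0 of both.

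Several inflammatory genes were lower in the knock-in over the 9 conditions, and the fatty acid desaturase Scd1 was higher in each of them. Saa3 (ENSMUSG00000040026.7, chromosome 7, 46711998 to 46715676), an acute-phase serum amyloid, was lower, at -6.46 ± 0.25 on the log2 scale over the 9 pairs (adjusted p = 2.2e-08, lower in 9 of 9), reaching 2234 CPM in wild-type and 31.9 CPM in knock-in cells at 8 h of LPS. Il12b (ENSMUSG00000004296.12, chromosome 11, 44400063 to 44414033) was lower, at -4.25 ± 0.39 (adjusted p = 4.1e-05), the scavenger receptor Marco at -3.52 ± 0.26 (9.4e-06) and Il1b (ENSMUSG00000027398.11, chromosome 2, 129364570 to 129371139), the gene of interleukin 1 beta, at -2.80 ± 0.21 (9.2e-06). Scd1 (ENSMUSG00000037071.2, chromosome 19, 44394451 to 44407709) was higher by 2.95 ± 0.12 (adjusted p = 2.3e-08) and already differed before stimulation, at 24.1 CPM in wild-type and 221.6 CPM in knock-in cells. Other genes lower in the knock-in were Scube3 (-3.53 ± 0.27), the chemokine Cxcl3 (-3.09 ± 0.46, 8 of 9 pairs), the ferroxidase Cp (-3.07 ± 0.20), Dach1 (-2.88 ± 0.26), Arhgef37 (-2.82 ± 0.33), the fatty acid receptor Gpr84 (-2.78 ± 0.25), the basement membrane collagen Col4a1 (-2.78 ± 0.23) and the adhesion molecule Sele (-2.74 ± 0.56, 8 of 9). Higher were Fam110c (2.19 ± 0.33, 8 of 9), the immunoglobulin heavy chain gene Ighm (2.06 ± 0.12), Nptx1 (2.04 ± 0.29) and the calcium channel genes Cacna1b (2.03 ± 0.22) and Cacnb4 (1.95 ± 0.36, 8 of 9). The same held for Emp2 (1.79 ± 0.09), Dhrs9 (1.71 ± 0.19), Iigp1 (1.70 ± 0.17), Fat3 (1.69 ± 0.13), the deiodinase Dio2 (1.68 ± 0.12) and Mb21d2 (1.59 ± 0.28, 8 of 9).

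**Figure D2:**
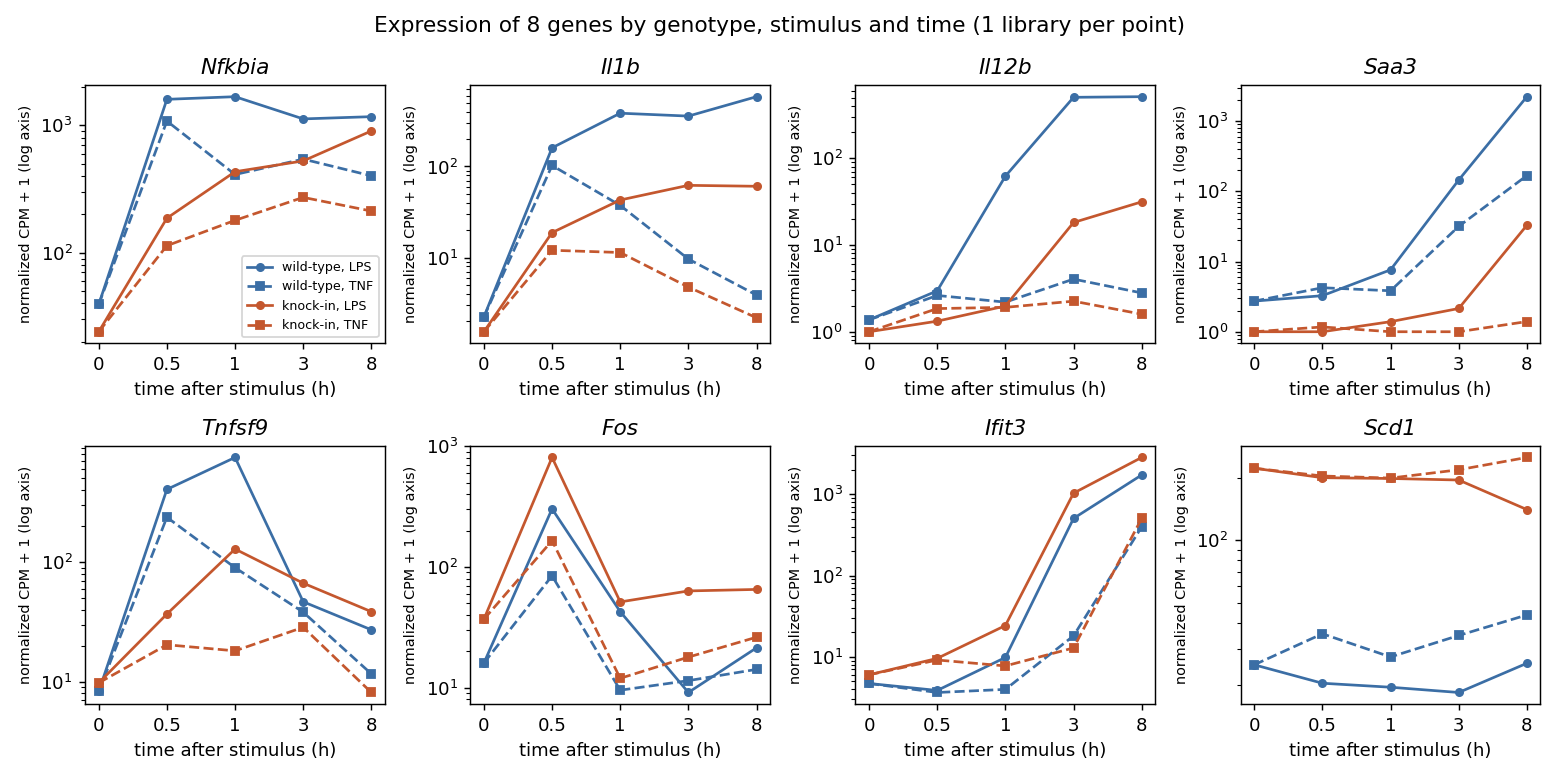
Normalized CPM plus 1 (log axis) of 8 genes against time after the stimulus (h, evenly spaced), with 1 library per point, wild-type in blue, knock-in in orange, LPS as solid and TNF as dashed lines. Saa3 stays far below wild-type in the knock-in after both stimuli and Il12b after LPS, Nfkbia lies below wild-type and nears it at 8 h of LPS (1169 against 902 CPM), and Scd1 lies above wild-type in each condition.

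Part of the genes on the NF-kB target lists were lower in the knock-in over the 9 conditions. Of 14 NF-kB feedback and family genes 7 were lower and 0 higher (10 and 0 adjusted over the list alone), including the inhibitors Nfkbie (-2.02 ± 0.38) and Nfkbia (-1.51 ± 0.33) and the family member Relb (-1.21 ± 0.16). Inflammatory cytokines were lower at 7 and higher at 1 of 16 (9 and 2), among them the neutrophil growth factor Csf3 (-4.01 ± 0.39). The values of Csf3 and Il12b come from the LPS pairs, since after TNF Csf3 had 0 counts against 1 and Il12b was not called (-1.04 ± 0.48, adjusted p = 0.280). Survival and adhesion targets were lower at 7 of 18 (9), with the adhesion molecule Icam1 (-2.19 ± 0.38), the antioxidant enzyme Sod2 (-1.41 ± 0.24) and the death receptor Fas (-1.18 ± 0.26). Late LPS effector genes were lower at 12 and higher at 2 of 22 (14 and 2), including the arginase Arg2 (-1.95 ± 0.27). Chemokines went both ways, with 6 lower and 3 higher of 15 (7 and 4), from Cxcl1 (-3.35 ± 0.29) to Ccl8 (1.55 ± 0.21). Camera called late effector genes (median -1.15, adjusted p = 7.2e-13) and cytokines (-0.75, 5.2e-06) lower, also with an estimated correlation. Its calls for NF-kB feedback genes (median -0.74, adjusted p = 8.8e-07) and survival targets (-0.44, 6.0e-05) were lost, at adjusted p = 0.0902 and 0.161 with an estimated correlation, and chemokines were not called (adjusted p = 0.0951).

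Of 30 interferon-stimulated genes 15 were higher and 0 lower (16 and 1 adjusted over the list alone, 9 and 0 with library totals), such as Oasl1 (1.33 ± 0.18), Ifi44 (0.85 ± 0.18) and Ifit3 (0.76 ± 0.19). Immediate early genes were higher at 10 and lower at 1 of 22 (10 and 2), with Dusp1 (1.47 ± 0.23), a phosphatase of MAP kinases, and Fos (1.16 ± 0.22) higher and Maff (-1.05 ± 0.12) lower. Both camera calls, adjusted p = 2.5e-07 and 0.0063, were lost at adjusted p = 0.185 and 0.0932 with an estimated correlation. Glycolysis genes were higher at 12 of 16 (13, with 1 lower), including the lactate exporter Slc16a3 (0.96 ± 0.07), Tpi1 (0.52 ± 0.05) and Pgk1 (0.49 ± 0.09), and the call held (adjusted p = 1.6e-10, and adjusted p = 0.0292 with an estimated correlation). Cholesterol synthesis genes were higher at 10 of 16 (13), with Sc5d (0.46 ± 0.05) and Insig1 (0.43 ± 0.12), called at adjusted p = 2.4e-08 but at adjusted p = 0.0905 with an estimated correlation. Macrophage identity genes were higher at 8 and lower at 3 of 17 (9 and 3, adjusted p = 0.00025, and adjusted p = 0.0292 with an estimated correlation), with Fcgr1 (0.92 ± 0.09) and the lipoprotein gene Apoe (0.51 ± 0.04) above and the chemokine receptor Cx3cr1 (-1.37 ± 0.32) below wild-type. Proliferation genes were lower at 9 and higher at 1 of 20 (11 and 1, adjusted p = 0.0012, and adjusted p = 0.0420 with an estimated correlation), from Mki67 (-0.37 ± 0.11) and Mcm3 (-0.28 ± 0.05) to Pcna (0.38 ± 0.09). Antigen presentation genes split, with 5 higher and 4 lower of 16 (5 and 5, or 3 higher and 5 lower with library totals). Lower were the class II genes H2-Eb1 (-1.67 ± 0.13), Cd74 (-1.63 ± 0.13) and H2-Aa (-1.49 ± 0.16), so the list's median was 0.02, its mean -0.27 and its test downward (adjusted p = 0.0434, and adjusted p = 0.445 with an estimated correlation). TLR4 and TNF receptor signalling had 3 higher and 2 lower of 20 (4 and 2, or 3 higher and 4 lower with library totals, adjusted p = 0.329), with the receptor Tlr4 at 0.51 ± 0.12.

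Markers of other cell types also differed between the genotypes. All 7 tested extracellular matrix and stromal genes of 12 on the list were lower in the knock-in (7 adjusted over the list alone), including Col1a2 (-1.83 ± 0.15), Sparc (-1.82 ± 0.16) and Col5a1 (-1.58 ± 0.13), with a median of -1.53 (adjusted p = 1.5e-18). Col1a2 stood at 69.4 CPM in wild-type and 23.5 CPM in knock-in cells before stimulation. Neutrophil markers were lower at 8 and higher at 1 of 11 (8 and 1), with the granule genes Mpo (-1.97 ± 0.17), Elane (-1.88 ± 0.37) and Prtn3 (-1.88 ± 0.24) below wild-type (adjusted p = 1.0e-09). Both calls held with an estimated correlation. Dendritic cell markers were lower at 2 of 5 (3), Cd209a at -3.50 ± 0.43 and Flt3 at -1.05 ± 0.28, called at adjusted p = 0.0091 but at adjusted p = 0.0905 with an estimated correlation. Of 2 lymphocyte markers the cytokine receptor gene Il7r was higher (0.62 ± 0.07), the single mast cell gene, Hdc, did not pass (-0.34 ± 0.16, adjusted p = 0.147, but 1 lower adjusted over the list alone), no erythroid gene of 8 was tested, and of the sex-linked genes Xist did not differ (0.01 ± 0.07, adjusted p = 0.949). The stromal and neutrophil shifts were present in the same libraries as the lower inflammatory and class II genes. In all, edgeR called 2232 genes, 1162 higher and 1070 lower, of which 99 and 352 changed at least 2-fold. With library totals 705 were higher and 1823 lower (27.9% higher against 52.1%).

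After LPS several secreted mediators stayed below wild-type levels in the knock-in. Over the 4 LPS pairs Saa3 was lower, at -6.20 ± 0.24 (adjusted p = 4.5e-07), Il12b at -4.57 ± 0.21 (1.1e-06), Cxcl3 at -4.24 ± 0.39, Csf3 at -4.13 ± 0.42, Marco at -4.13 ± 0.35, Cxcl1 at -3.60 ± 0.27 and Il1b at -3.04 ± 0.23, each in 4 of 4 pairs. At 3 h of LPS Il12b stood at 502 CPM in wild-type and 17.2 CPM in knock-in cells. Gpr84 (-3.44 ± 0.28), Scube3, Cp (-3.22 ± 0.20), Arhgef37, Ntng2 and Shisa3 completed the largest decreases. Higher in the knock-in were Scd1 (3.21 ± 0.14), Nptx1 (3.07 ± 0.49), Cacnb4 (2.97 ± 0.35), Fam110c (2.70 ± 0.40) and the VEGF receptor gene Flt1 (2.62 ± 0.26). So were Cacna1b (2.36 ± 0.38), Tnfsf18 (2.13 ± 0.28), Ighm (2.08 ± 0.22), the angiogenic factor Vegfa (2.05 ± 0.25), Dhrs9 (1.99 ± 0.28) and the G-protein regulator Rgs2 (1.89 ± 0.13). Of the lists, late effector genes were lower at 12 and higher at 2 of 22 (13 and 3 adjusted over the list alone, adjusted p = 7.1e-17), cytokines lower at 6 and higher at 1 of 16 (8 and 1, adjusted p = 1.2e-14), and chemokines lower at 5 and higher at 2 of 15 (5 and 3, adjusted p = 0.00024). Neutrophil markers were lower at 8 of 11 (9, adjusted p = 4.0e-10), matrix genes at 5 of 7 (6, adjusted p = 3.3e-12), and glycolysis genes were higher at 11 of 16 (12, adjusted p = 1.9e-10), and these 6 calls held with an estimated correlation. NF-kB feedback genes were lower at 4 of 14 (8) and survival targets at 4 of 18 (9, or 8 of 18 with library totals), with Relb at -1.42 ± 0.22, Sod2 at -1.90 ± 0.22 and Icam1 at -2.61 ± 0.55, at adjusted p = 3.8e-07 and 5.5e-08 but at adjusted p = 0.0708 for both with an estimated correlation. Interferon-stimulated genes were higher at 7 of 30 (17, or 2 of 30 with library totals), Ifit3 by 1.05 ± 0.24 and Ifit1 by 0.81 ± 0.16. Their call (adjusted p = 1.7e-07) and those of immediate early genes (7 higher and 1 lower, 0.0142), macrophage identity (8 and 1, 0.0017), proliferation (1 and 2, 0.0473) and cholesterol synthesis (6 and 0, 2.8e-05) were lost, at adjusted p = 0.231, 0.218, 0.0708, 0.218 and 0.227 with an estimated correlation. Antigen presentation, with 3 higher and 4 lower (1 and 4 with library totals) and a median of 0.13 against a downward test, was not called (adjusted p = 0.143), nor were TLR4 and TNF receptor signalling (0.486) and dendritic cell markers (0.127). edgeR called 1130 genes, 619 higher and 511 lower, 581 in all without the LPS 3 h pair, and 421 higher and 641 lower with library totals (39.6% higher against 54.8%).

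After TNF the acute-phase gene Saa3 and several matrix genes were lower in the knock-in. Saa3 was lower in 4 of 4 pairs, with 3 counts in the 4 knock-in libraries against 1160 in wild-type, 324-fold lower (111 to 1576, adjusted p = 2.1e-06). Scube3 (-4.00 ± 0.42), Arhgef37 (-3.05), Marco (-3.03 ± 0.31), Sorbs2 (-2.98 ± 0.48) and Dach1 (-2.91 ± 0.42) were lower too. Col4a2 (-2.88 ± 0.27), Col4a1 (-2.66 ± 0.38), the hyaluronan-degrading Cemip (-2.79 ± 0.26), the complement gene C3 (-2.79 ± 0.34), the citrate transporter Slc13a5 (-2.71 ± 0.51), the cytokine Lif (-2.59 ± 0.55), Il1b (-2.28 ± 0.32), Acod1 (-2.17 ± 0.46) and Cxcl1 (-2.16 ± 0.50) were lower as well. Scd1 (2.67 ± 0.13), Sox7 (2.53 ± 0.40), Ighm (2.01 ± 0.20), Cacna1b (1.99 ± 0.32), Emp2 (1.86 ± 0.12) and the eotaxin receptor Ccr3 (1.80 ± 0.32) were higher, as were Dio2 (1.78 ± 0.18), Fat3 (1.62 ± 0.21), Nptx1 (1.60 ± 0.37), Tgm1 (1.55 ± 0.28), Dusp1 (1.53 ± 0.27) and Dhrs9 (1.52 ± 0.28). Late effector genes were lower at 9 and higher at 1 of 22 (13 and 1 adjusted over the list alone, adjusted p = 2.4e-11) and matrix genes lower at 5 of 7 (7, adjusted p = 3.6e-30), Col1a2 at -2.27 ± 0.18, both also with an estimated correlation. The other list calls were lost with an estimated correlation. They were NF-kB feedback genes with 2 lower (3, adjusted p = 5.5e-06, and adjusted p = 0.0942 with an estimated correlation), cytokines with 2 lower (3, 0.0010 and 0.0919), survival targets with 1 lower (2, 0.0017 and 0.239), interferon-stimulated genes with 4 higher (6, or 1 with library totals, 0.00032 and 0.323), immediate early genes with 4 higher and 1 lower (8 and 2, 0.0015 and 0.114) and antigen presentation with 2 higher and 4 lower (3 and 4, or 1 and 4 with library totals, 0.0020 and 0.295). They also included macrophage identity with 6 higher (8 and 3, 0.0027 and 0.0834), proliferation with 0 in each direction (4 lower, also 4 with library totals, 0.0015 and 0.0834), cholesterol synthesis with 5 higher (7, 1.9e-07 and 0.116), glycolysis with 6 higher (10, 1.4e-06 and 0.0834), neutrophil markers with 6 lower and 1 higher (7 and 1, 3.9e-05 and 0.0834) and dendritic cell markers with 1 lower (4, 0.00078 and 0.0834). Cd209a of that last list had 3 knock-in counts against 52, 14.5-fold lower (4.71 to 72.8). Chemokines (2 lower, adjusted p = 0.162) and TLR4 and TNF receptor signalling (1 higher, 0.266) were not called. edgeR called 602 genes, 273 higher and 329 lower, and 178 higher and 434 lower with library totals (29.1% higher against 45.3%). The count was 353, 301, 287 and 285 without the TNF 0.5, 1, 3 and 8 h pairs and 912 without the LPS 8 h pair.

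Calls after LPS and after TNF, which share no library, overlapped at 214 genes higher and 244 genes lower in the knock-in, where independent lists would share 14.9 and 14.9, and 1 gene was called in opposite directions. This overlap is not a replication, since both comparisons used the same estimate of spread and no separate cultures were named. A difference between genotypes or cultures already present before stimulation enters both lists. The difference of the genotype effect between LPS and TNF called no gene with edgeR, with 578 genes under an unadjusted p of 0.05 and 0 by limma-voom. The gene nearest to a call was Flt1, 3.02 ± 0.45 higher after LPS than after TNF (adjusted p = 0.170), chosen after its values were seen. DESeq2 called 4 genes, also named after their values were seen: Rgs2 (0.97 ± 0.19 with edgeR, adjusted p = 0.632), the thioredoxin inhibitor Txnip (0.65 ± 0.11, 0.499), Il12b (-3.52 ± 0.64, 0.558) and the stress gene Gadd45g (1.62 ± 0.23, 0.170). Without a filter on low counts 3 were called (Txnip, Flt1 and Gadd45g), and without the LPS 0.5 h pair Gadd45g alone. By rule the most expressed members of lists without a call were Tnfaip3 (-0.25 ± 0.90), Tnf (-0.52 ± 0.69), Rsad2 (0.15 ± 0.32), Tnfrsf1b (-0.47 ± 0.22) and Acod1 (0.43 ± 0.63). Camera placed matrix genes (median 0.68, adjusted p = 2.8e-06), glycolysis (0.19, 0.0041), interferon-stimulated genes (0.27, 0.0296) and dendritic cell markers (0.46, 0.0296) higher and survival targets (-0.39, 0.00056), neutrophil markers (-0.32, 0.0017), chemokines (-0.18, 0.0108) and late effector genes (-0.30, 0.0247) lower. None held, at adjusted p = 0.226, 0.312, 0.691, 0.250, 0.297, 0.226, 0.226 and 0.226 with an estimated correlation in that order. Adjusted over the list alone 2 matrix genes were higher and 1 cytokine, 3 late effector genes and 1 neutrophil marker lower.

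No single gene passed as differing in its genotype effect between stimulated and unstimulated cells, a comparison that rests on 1 unstimulated pair. edgeR called 0 genes, with 200 under an unadjusted p of 0.05 and 0 by limma-voom. The pattern receptor gene Tlr2, named after its values were seen, came nearest (-1.92 ± 0.24, adjusted p = 0.0639) and was the 1 gene called by DESeq2, without a filter on low counts and without the LPS 0.5 h pair. Tlr2 stood at 56.9 CPM in wild-type and 40.2 CPM in knock-in cells before stimulation, and at 1462 and 197 CPM at 3 h of LPS. Listed by rule, Tnfaip3 stood at -1.34 ± 1.36, Tnf at -0.47 ± 1.21, Acod1 at -1.39 ± 1.32 and Klf6 at 0.28 ± 0.14. Camera called NF-kB feedback genes (median -0.47, adjusted p = 0.00045), survival targets (-0.32, 0.00045), chemokines (-0.75, 0.0067), antigen presentation (-0.24, 0.0067) and cytokines (-0.90, 0.0353) lower, none of which held at adjusted p = 0.447, 0.447, 0.259, 0.702 and 0.447 with an estimated correlation. Adjusted over the list alone, 0 genes passed in any list. In simulated data this comparison recovered 80.3% of changes of 2 on the log2 scale, 35.8% of changes of 1 and 0% of changes of 0.5, with 9.41% false calls.

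Before stimulation, with 1 library per genotype and no test, the NF-kB feedback genes had a median log2 ratio of -0.16, with 12 of 14 members lower, and cytokines stood at -0.02. In the LPS pairs the feedback list stood at -0.65, -1.61, -1.07 and -0.09 at 0.5, 1, 3 and 8 h, and in the TNF pairs at -0.63, -0.998, -0.68 and -0.24. Cytokines stood at -1.61, -1.85, -0.62 and -0.42 after LPS and at -1.21, -0.25, -0.82 and -0.35 after TNF. Interferon-stimulated genes had medians of 0.34 before stimulation, 0.37 to 0.54 after LPS, and 1.00, 0.64, -0.32 and 0.05 after TNF, where at 3 h 22 of 30 members were lower in the knock-in library with the low mitochondrial share of 0.404%. Unstimulated glycolysis genes stood at 0.41, cholesterol synthesis genes at 0.24, neutrophil markers at -1.08 and matrix genes at -1.45.

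**Figure D3:**
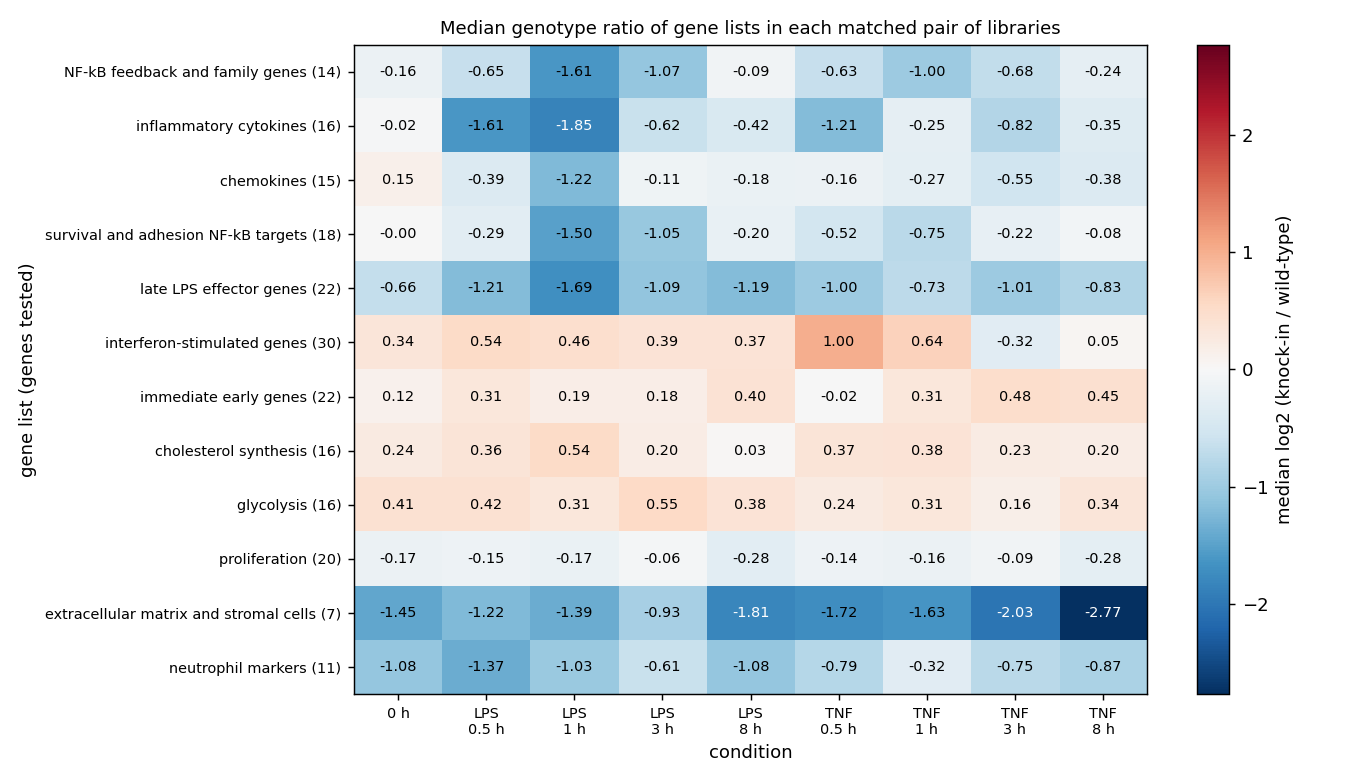
Median log2 ratio of knock-in to wild-type for 12 gene lists (vertical axis, with the number of genes tested) in each of the 9 matched pairs of libraries (horizontal axis), blue for lower and red for higher in the knock-in. NF-kB feedback genes are lowest at 1 h (-1.61 after LPS) and near 0 at 8 h of LPS (-0.09), and matrix genes are below wild-type in each pair.

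The genotype effect changed with time for a small set of genes. The costimulatory ligand Tnfsf9 (ENSMUSG00000035678.7, chromosome 17, 57105385 to 57107757) was much lower in the knock-in at the early times than at the late ones. The difference between late and early effects was 3.09 ± 0.37 (adjusted p = 0.015). The ratio of knock-in to wild-type rose in 4 of 4 differences, taken as 3 h minus 0.5 h and 8 h minus 1 h of each stimulus. At 0.5 h of LPS Tnfsf9 stood at 404 CPM in wild-type and 35.8 CPM in knock-in cells, and at 3 h at 45.6 and 65.7 CPM. Mir155hg (2.69 ± 0.31), the transcription factor Egr2 (2.59 ± 0.33), the GTPase gene Gem (2.55 ± 0.23, adjusted p = 0.00085), Mtus1 (1.76 ± 0.19), the deadenylase Noct (1.70 ± 0.22), Rab15 (1.62 ± 0.21) and the MAX partner Mxd1 (1.59 ± 0.20) shifted the same way. Cebpd, a late-acting amplifier of LPS responses, moved oppositely (-1.48 ± 0.19), with log2 ratios of 0.39 and -0.34 at 0.5 and 1 h of LPS and -1.68 and -1.40 at 3 and 8 h. Prrg1 (-1.38 ± 0.26), Ift57 (-1.18 ± 0.19), the interferon-induced Oasl2 (-0.83 ± 0.12), Stk17b (-0.77 ± 0.12), Acsl1 (-0.72 ± 0.13) and Zfand5 (-0.69 ± 0.13) followed it. List members past the threshold included Cflar (0.52 ± 0.09) and Nlrc5 (-0.64 ± 0.11), while Tnfaip3 (2.06 ± 0.42, adjusted p = 0.132) and Cxcl10 (2.09 ± 0.51, 0.193) did not pass.

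edgeR called 45 genes, 36 with a late effect above the early one and 9 below (19 and 10 with library totals, 65.5% above against 80.0%, median shift -0.10). Without the LPS 0.5, 1, 3 and 8 h pairs the count was 13, 15, 68 and 76, and without the TNF 0.5 and 3 h pairs 16 and 73. NF-kB feedback genes shifted upward by camera (median 0.79, adjusted p = 9.1e-05) with 0 of 14 called singly (4 up and 1 down adjusted over the list alone), and cytokines (0.55, adjusted p = 0.0150), survival targets (0.34, 0.0295) and immediate early genes (0.12, 0.0480) had 1 call each (2 up and 2 down, 1 and 1, and 4 and 1). Interferon-stimulated genes (-0.35, adjusted p = 3.9e-13), with 1 called down (10), antigen presentation genes (-0.14, 0.0106), with 1 (2), and cholesterol synthesis genes (-0.23, 2.7e-06), with 0 (6), shifted downward. No list call held, at adjusted p = 0.346, 0.275, 0.865, 0.703, 0.275, 0.766 and 0.275 with an estimated correlation in that order.

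Genes that a stimulus raised at least 2-fold were not called lower in the knock-in as a set after that stimulus, but the result for TNF depended on the size of the induction. Of 2464 genes that LPS raised at least 2-fold in both genotypes together, 280 were higher and 227 lower after LPS in the knock-in (383 and 289 adjusted over the list alone), with a median of 0.06 and a camera test at p = 0.212 by preset and p = 0.579 by estimated correlation. Of 870 TNF-induced genes 53 were higher and 73 lower after TNF (95 and 112), with a median of -0.03 (p = 0.459, and p = 0.723 by estimated correlation). Of 407 TNF-induced genes with a log2 fold change of 2 or more 21 were higher and 46 lower after TNF, with a median of -0.11. Camera called that set lower with the preset correlation (p = 0.0042) and not with an estimated correlation (p = 0.313). Among the lower LPS-induced genes were Saa3, Il12b, Csf3 and Il1b, and among the higher Oasl1, Ifit3 and Ccl8. These sets were chosen on the same libraries, so the counts are not independent evidence of a direction.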

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

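Tests of splits over the 9 conditions, after LPS and of LPS against TNF effects were chosen only after the result was seen. So were the tests of stromal cells, weaker or later stimulation, culture, library composition, single pairs out of line and strain variants.

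A test of the difference itself singled out 45 genes whose genotype effect differed between late and early times. The late effect lay above the early one for Tnfsf9 (3.09), Mir155hg (2.69), Egr2 (2.59), Gem (2.55), Mtus1 (1.76), Noct (1.70), Rab15 (1.62) and Mxd1 (1.59), on the log2 scale. It lay below for Cebpd (-1.48), Prrg1 (-1.38), Ift57 (-1.18), Oasl2 (-0.83), Stk17b (-0.77), Acsl1 (-0.72) and Zfand5 (-0.69). Of 35 splits of the libraries only the real 1 gave as many genes, with 1 gene as the highest other. Fewer splits keep LPS and TNF times balanced on both sides, as the real one does, and their share was not computed. A chance difference between cultures would follow the real labels too, so chance is not excluded. Library composition that changes with time is argued against as the whole source by size, since the smallest called change was 0.44 and library totals shifted the median by 0.10, with which 45 of 45 genes kept their sign and 28 stayed called. A single pair of libraries out of line is argued against as the whole source. Without the LPS 0.5 h pair 13 of the genes were still called, the fewest of any pair left out. No fit left out a time for both stimuli together, so a time point out of line after both stimuli stays open. A genotype effect on timing stays open as a hypothesis, beside a difference between cultures, for which there was 1 library per genotype and condition.

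Among the cytokine, chemokine and late effector genes, 25 were lower in the knock-in over the 9 conditions. The lowest of the stromal list and the basement membrane collagens was Col4a1 (-2.78). Below it by more than 2 standard errors lay 4 of the 25, the largest decreases (Saa3, Il12b, Csf3 and Marco). Loss of stromal cells would not alone lower these 4 so far, if no other stromal gene fell further. That was not tested, and Scube3, a gene outside the stromal list, stood at -3.53 ± 0.27. Fewer stromal cells in the knock-in culture therefore stay open as an explanation, for these 4 as for the other 21. Weaker or later stimulation of the knock-in cultures also stays open: of 82 genes induced by LPS at 0.5 h 43 were lower in the knock-in (52.4%), and of 36 induced by TNF 19 (52.8%), but 1 pair of libraries per stimulus gives these shares no spread. A difference between the cultures other than the edited gene cannot be told apart from genotype, with 1 library per genotype and condition. The edited gene therefore stays a candidate explanation only.

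Genes that differed over the 9 conditions were not concentrated near Rela. Within 10 Mb 36 of 194 tested genes were called and elsewhere 2196 of 11114 (odds ratio 0.925, 95% limits 0.624 to 1.34, Fisher's exact p = 0.717). Strain variants carried along beside the edited gene stay open, since a window of 194 tested genes could not hold most of the calls. Carried variants that act on genes elsewhere, or that lie further along the chromosome, were not tested. Of 100 splits of the libraries 1, the real one, gave as many as 2232 genes, with 355 as the highest other. So none of the other splits tried, with genotype labels swapped within conditions, gave as many. A chance difference between cultures would follow the real labels in each pair, so the splits cannot exclude it. After LPS 1 of 32 splits gave as many as 1130 genes, with 920 as the highest other, and after TNF 1 of 32 gave as many as 602, with 0 as the highest other. Only 8 splits part all 4 time pairs as the real one does, with 2 genes as the highest other after LPS and 0 after TNF, and 8 are too few for a share under 0.05. For the difference of the genotype effect between LPS and TNF the real count was 0, which all 35 splits reach, so splits decide nothing there (highest other 45). Between LPS and TNF 1 of 100 splits gave as many as 5529 genes, with 5462 as the highest other. These splits swapped the stimuli within single genotypes and times. A swap of 0.5 h libraries alone changes little, since 5 genes separated the stimuli at that time. A count close to the real one can therefore arise by construction.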

How the results depend on the processing

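Scaling by library totals was chosen only after the result was seen. For single named genes, DESeq2 gave 438 values with the same direction and side of the threshold, 12 weaker, 3 stronger and 1 reversed, limma-voom 439, 14, 0 and 1, no filter 417, 34, 3 and 0, and library totals 430, 19, 0 and 5. The fits that leave out a condition gave 3631, 281, 5 and 8, and the stricter filter 409, 1, 0 and 0. All 454 kept both with DESeq2 size factors. Of 144 list tests 52 lost their call with an estimated correlation. The other 92 stayed on the same side of the threshold, which includes lists called with neither correlation. No paired analysis was possible by replicate because each group had 1 library.

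Without a filter on low counts 3 genes passed for the difference of the genotype effect between LPS and TNF, 1 between stimulated and unstimulated cells and 147 between late and early times, and with DESeq2 4, 1 and 122. With library totals the last count was 29. The cause was not tested. Leaving out each condition gave 581 (LPS 3 h) to 1146 genes for genotype after LPS, 285 (TNF 8 h) to 912 (LPS 8 h) after TNF, 0 to 1 (LPS 0.5 h) for LPS against TNF effects and for stimulated against unstimulated effects, and 13 (LPS 0.5 h) to 76 (LPS 8 h) for late against early effects. It gave 1100 (TNF 8 h) to 4201 (LPS 8 h) for the TNF response and 1932 (TNF 8 h) to 5970 (LPS 0.5 h) for LPS against TNF. At a log2 fold change of 2, which keeps fewer genes by construction, 171 LPS-induced genes were higher and 159 lower, and 21 TNF-induced genes were higher and 46 lower.

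Directions reversed with library totals in the LPS response for Hk2 (-1.59), Il7r (-0.78) and Xist (-1.14), and in LPS against TNF for Il7r (-0.30) and Xist (-0.22). Lad1 in the TNF response was 3.43 with DESeq2 and 3.19 with limma-voom, where the cause was not tested. Leaving out the time of the largest change moves a response to another time by construction, and ranges were -8.07 to 0.73 for Coro2b and -0.69 to 1.57 for Hk2 after LPS. After TNF they were -4.57 to 2.33 for Flt4, -3.84 to 3.44 for Lad1, -1.76 to 5.07 for Egr1, -0.20 to 3.10 for Tap1, -0.84 to 2.04 for Fcgr1 and -1.17 to 0.51 for Gapdh. At this depth genes with few counts carry wide counting intervals.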

Other observations

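The genes in this paragraph were chosen only after their values were seen, and no list of them was tested. The hypoxia and monocyte tests below were chosen before their own results were seen. They were prompted by the glycolysis, class II and granule results in the same libraries. Over the 9 conditions some single genes of lipid handling were higher in the knock-in and others did not pass. Lpl, a lipase of triglyceride-rich lipoproteins, was higher by 1.16 ± 0.04 on the log2 scale (adjusted p = 4.8e-09), the phospholipid transfer gene Pltp by 1.45 ± 0.09, the desaturase Scd2 by 1.15 ± 0.05, and the cholesterol exporters Abcg1 and Abca1 by 1.13 ± 0.06 and 0.89 ± 0.16. Lpcat3 (0.60 ± 0.05), Pparg (0.60 ± 0.14), Cd36 (0.57 ± 0.05), Srebf1 (0.47 ± 0.05) and Fads1 (0.44 ± 0.04) were higher too. Fasn (0.30, adjusted p = 0.146), Elovl6 (0.18, 0.103) and Mylip (0.26, 0.208) did not pass. Ifnb1 was higher by 1.38 ± 0.36 (adjusted p = 0.026), with 27.9 CPM in wild-type and 189 CPM in knock-in cells at 3 h of LPS, and Tlr2 lower by -2.24 ± 0.21.

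Since glycolysis genes were higher in the knock-in, hypoxia response genes may be higher as well. Of 13 tested genes of 14, 9 were higher and 0 lower, with a median of 0.27 (camera with an estimated correlation, p = 0.0128), including the oxygen sensor Egln3 (1.45 ± 0.14) and the mitophagy gene Bnip3 (0.95 ± 0.12). Since class II and granule genes were lower, monocyte genes may be lower too, and of 7 tested genes of 8, 3 were lower and 0 higher, with a median of -0.53 (camera with an estimated correlation, p = 0.00496), including Hp (-2.53 ± 0.25) and Vcan (-1.02 ± 0.22). Both p-values are unadjusted and come from the libraries that prompted the lists, so they are not independent evidence. Both differences are confounded with culture, since each genotype had 1 library per condition.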
